A study of Homo sapiens with 98 samples.

How the data were processed

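RNA was measured on Affymetrix HG-U133 Plus 2.0 arrays in bone marrow of children with B-precursor acute lymphoblastic leukaemia. Per the labels, mononuclear cells were enriched by Ficoll density gradient and cryopreserved, and total RNA was amplified in a double round and labelled with biotin. The authors deposited 1 intensity value per probe set and array, on a linear scale, with positive values throughout and similar array medians. The sources used here do not state how the probe sets were summarised, corrected for background or normalised. The table held 54675 probe sets for 98 arrays.

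An offset of 16 was added to each deposited intensity and log2 was taken, as fixed before the data were examined for a table on a linear scale. Gene symbols came from the annotation of the array, which listed 42898 probe sets, 41097 of them with 1 symbol. The 1801 probe sets with several symbols and the 11777 not listed were left out, as were control probe sets and 61 probe sets of XIST and Y-linked genes. Of the 41030 probe sets kept, the one with the highest mean over all arrays stood for its gene, which gave 19738 genes, 9227 with 1 probe set and 10511 with several. No filter on dim probe sets was applied. The number of probe sets that point the same way is given for passing named genes where most of the others did not.

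Patient numbers in the titles paired the samples. The pairing was checked without genes of the sex chromosomes, HLA, immunoglobulin or T-cell receptor segments: the deviations from the group mean of the 2 arrays of a patient correlated above 0.1 in 45 of 49 pairs over 18893 genes, with a median of 0.461, against a median of -0.024 between patients. In most patients both arrays also lay on the same side of a split in the spread of values, described below. That split may raise the correlation within patients, so the check cannot settle the pairing. All 49 pairs were kept. The highest correlation between arrays was 0.989, so no array was a copy of another.

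The 6 comparisons were fixed before the data were examined, as were the gene lists, the named genes rule and most alternatives. Changes from diagnosis to relapse were tested with limma 3.58.1 in R 4.3.3 on within-patient differences, for all 49, the 29 early and the 20 late pairs, and the early and late changes were compared with the group as the term. Late and early patients were compared at diagnosis and at relapse without a block, since the patients differ. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. For 37 gene lists covering proliferation, drug handling, DNA repair, signalling, metabolism, stress, B-cell stages and other marrow cells, camera was run with a preset correlation of 0.01 and with an estimated correlation, and fry beside it. A list score is the mean log2 level of its measured members per array. Score changes were tested by two-sided permutation with 100000 resamples, flipping the signs of the pairs or permuting the patients' group labels, and adjusted over the 37 lists. The smallest p these resamples allow is 1e-05.

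For each comparison of relapse with diagnosis, the named genes were the 10 largest rises and the 10 largest falls among passing genes that moved that way in at least 60% of pairs, and up to 3 passing members of each list called by camera. For late against early they were the 5 largest passing genes on each side. Where fewer than 5 genes passed, the 5 with the smallest p were named. NR3C1, MSH6, TYMS, BIRC5, FOXM1, CDKN2A and IKZF1 were always named, and immunoglobulin and T-cell receptor segments never.

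The alternatives were a threshold of 0.1, no replicate block, quantile normalization, centring of arrays, a filter on dim probe sets, the mean of a gene's probe sets, every probe set singly, a variance trend with robust fitting, array quality weights, and covariates for RNA quality, other cell types and the mitosis score. RNA quality was the 3-prime minus 5-prime signal of the GAPDH and actin control probe sets. Others left out 2 early pairs out of order, or drew 20 early pairs at random. In each of these 2 pairs 1 array sat among the arrays of the late group, the relapse array in 1 pair and the diagnosis array in the other. By this order, the relapse array of each of these 2 pairs matched the diagnosis array of the other pair. In 1 of these 2 matches both arrays sat among the late group. Whether a label or a pairing was swapped was not tested. Leaving these pairs out was not run for late against early at diagnosis or at relapse. No offset before log2 and the interquartile range of the array as a covariate were added after seeing the data. The tests were run on simulated data, made from residuals of the real arrays with signs flipped or order shuffled, in a single draw per comparison. A change was added to 200 genes, split evenly between 1 and 0.5 log2 units. Genes with 1 log2 unit were recovered at 99% in all pairs, 96% in early, 93% in late, 74% in the difference of changes, 92% at diagnosis and 84% at relapse. In the same order, genes with 0.5 log2 units were recovered at 90%, 72%, 72%, 56%, 59% and 58%. Between 1 and 20 other genes were called. Scores, tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.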

Results

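Gene expression was measured in bone marrow from 49 children with B-precursor acute lymphoblastic leukaemia, a cancer of immature B cells. Each patient gave a sample at diagnosis and a sample at relapse, so the 98 arrays formed 49 pairs. The labels placed 29 patients in an early relapse group and 20 in a late relapse group, without the time that separates the groups. Array medians lay between 102 and 129 intensity units in all 4 groups, and the number of arrays limits the precision. The labels name no sorting of the cells, so each array measured leukaemic cells together with the other cells of the enriched marrow. Changes below are differences of log2 intensity with their SE, and list scores are means over the members of a gene list. The labels gave no scan date or batch, so no within-batch values could be computed.

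The first comparison asked which genes change between diagnosis and relapse within a patient, over all 49 pairs. At relapse, genes of cell division and DNA synthesis were higher, together with markers of granulocytes, monocytes, megakaryocytes and stroma. Markers of mature B cells and genes recurrently deleted in this leukaemia were lower. As list scores, these 2 falls also passed in the early pairs alone but not in the late pairs alone. The difference between the early and late changes did not pass for any list score. The limma test of the within-patient differences called 291 of 19738 genes, of which 192 rose and 99 fell, and 3140 genes had an unadjusted p under 0.05. Every probe set gave 276 higher and 261 lower, and the mean of a gene's probe sets 195 higher and 146 lower. Without the pairing (no replicate block), 21 genes passed.

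Among the genes of mitosis, 9 of the 32 measured members rose over all genes tested, and 30 adjusted over the list alone. FOXM1, a transcription factor that drives mitotic genes, rose by 0.69 ± 0.12 (SE, n = 49 pairs, higher in 37, adjusted p = 0.00183). BIRC5, which encodes the survival and cell division protein survivin, rose by 0.72 ± 0.16. GTSE1 rose by 0.31 ± 0.05 in the probe set used, and 4 of its 5 probe sets pointed that way. The mitosis list score rose by 0.49 ± 0.14 (higher in 35 of 49 pairs, adjusted permutation p = 0.00644). The camera call of this list, of DNA replication and of nucleotide synthesis did not hold with the estimated setting, at adjusted p = 0.114 with an estimated correlation for each. In DNA replication, 6 of 37 members rose over all genes tested and 25 adjusted over the list alone, among them MCM7 of the replicative helicase (0.51 ± 0.12), the origin recognition subunit ORC6 (0.41 ± 0.10, higher in 42 pairs), and the chromatin assembly factor CHAF1A (0.38 ± 0.10). The list score rose by 0.31 ± 0.09 (34 of 49 pairs, adjusted p = 0.0083). In folate and nucleotide synthesis, 3 of 30 members rose over all genes tested and 15 adjusted over the list alone. They were the ribonucleotide reductase subunits RRM2 (0.76 ± 0.18) and RRM1 (0.44 ± 0.11), and thymidine kinase TK1 (0.69 ± 0.14), and the score rose by 0.27 ± 0.08 (33 pairs, adjusted p = 0.00948). The homologous recombination and checkpoint score rose by 0.19 ± 0.07 (37 pairs, adjusted p = 0.0421), with 3 of 21 members higher over all genes tested and 8 adjusted over the list alone. These 3 were RAD51AP1 (0.65 ± 0.18), FANCI (0.52 ± 0.14) and the helicase RECQL4 (0.40 ± 0.09). The camera call of this list was lost, at adjusted p = 0.269 with an estimated correlation. With the marker scores of T cells, monocytes, granulocytes and erythroid cells as covariates none of these 4 scores passed. Mitosis then differed by 0.19 ± 0.13 (adjusted p = 0.676), DNA replication by 0.18 ± 0.10 and nucleotide synthesis by 0.18 ± 0.09 (both adjusted p = 0.613), and homologous recombination by 0.10 ± 0.08 (adjusted p = 0.728). The median change of the DNA replication genes went from 0.34 to 0.17, and that of nucleotide synthesis from 0.22 to 0.14.

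Markers of other marrow cells moved in the same pairs. The granulocyte and precursor score rose by 0.50 ± 0.14 (35 of 49 pairs, adjusted p = 0.00629), and 5 of its 26 members rose over all genes tested and 12 adjusted over the list alone. Lactoferrin (LTF) rose by 1.34 ± 0.35, the defensin DEFA4 by 1.16 ± 0.26, myeloperoxidase (MPO) by 1.11 ± 0.27, CEACAM6 by 0.91 ± 0.20 and CRISP3 by 0.59 ± 0.14. CRISP3 was dim, with means of 5.86 at diagnosis and 6.46 at relapse, below the median level of all probe sets (7.05). The monocyte and macrophage score rose by 0.39 ± 0.11 (32 pairs, adjusted p = 0.0083), with 5 of 26 members higher over all genes tested and 14 adjusted over the list alone. Lysozyme (LYZ) rose by 1.22 ± 0.31, VCAN by 1.15 ± 0.30, the scavenger receptor CD163 by 0.48 ± 0.13 and CD86 by 0.48 ± 0.12. The megakaryocyte and platelet score rose by 0.36 ± 0.09 (33 pairs, adjusted p = 0.00333), while the median change of its members was 0.14. In that list, 6 of 20 members were higher over all genes tested and 8 adjusted over the list alone. Of these, SPARC rose by 0.89 ± 0.19 and ITGB5 by 0.55 ± 0.12, while CTTN rose by 1.10 ± 0.22 in the probe set used and only 2 of its 5 probe sets pointed that way. The camera calls of these 3 lists ended, at adjusted p = 0.114 with an estimated correlation. The stromal and endothelial score rose by 0.23 ± 0.06 (32 pairs, adjusted p = 0.0053), and 2 of 23 members rose over all genes tested and 9 adjusted over the list alone. These were the chemokine CXCL12 (1.02 ± 0.23) and the adhesion molecule VCAM1 (0.71 ± 0.17). CXCL12 was higher in only 29 of 49 pairs, and its SD was 0.83 at diagnosis and 1.68 at relapse. The camera call of the stromal list gave adjusted p = 0.222 with an estimated correlation. Erythroid markers differed by 0.39 ± 0.20 (31 pairs, adjusted p = 0.132), T-cell markers by -0.06 ± 0.11 (adjusted p = 0.673) and markers of natural killer and cytotoxic cells by -0.15 ± 0.11 (adjusted p = 0.284), none of which passed as a score. Camera called the erythroid and natural killer lists, at adjusted p = 0.39 and 0.573 with an estimated correlation.

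**Figure D1:**
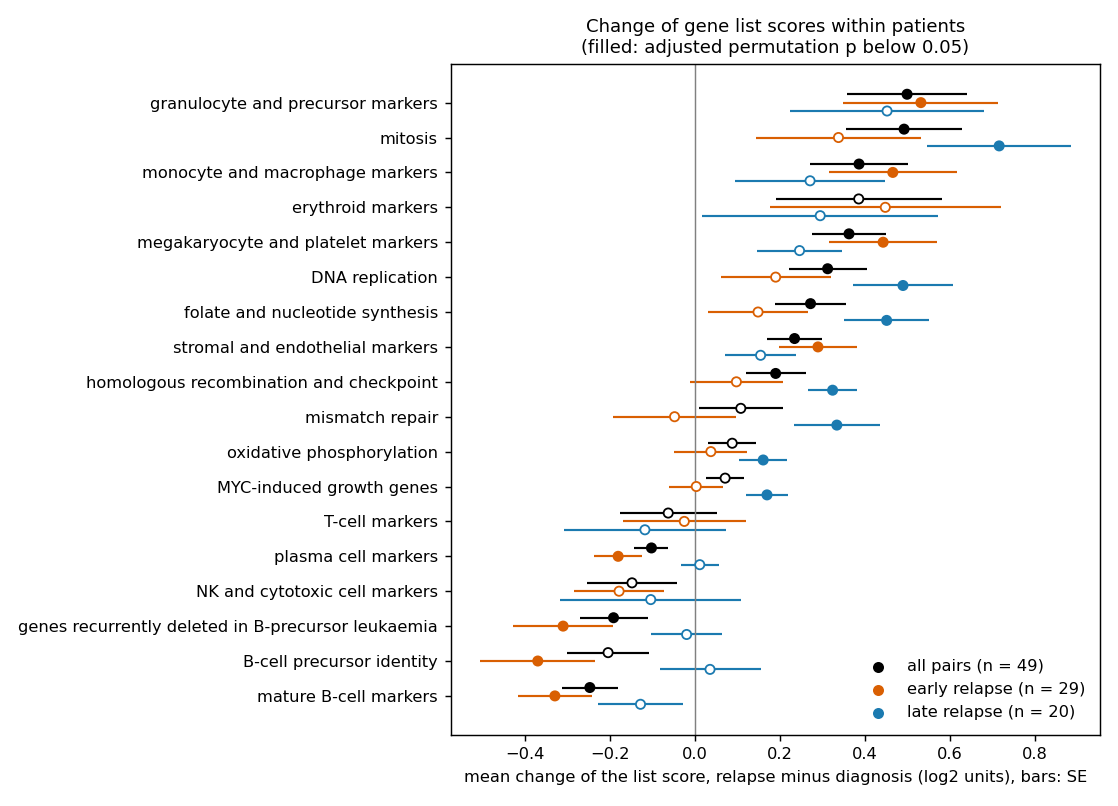
Mean change of gene list scores from diagnosis to relapse in log2 units, for all 49 pairs, the 29 early and the 20 late pairs. Bars are SE, and filled points have an adjusted permutation p below 0.05. In all pairs the mitosis score changed by 0.49 and the granulocyte score by 0.50, and in late pairs the mitosis score changed by 0.72, all 3 filled.

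Genes of the B lineage were among those that fell. The mature B-cell score fell by 0.25 ± 0.07 (lower in 32 of 49 pairs, adjusted p = 0.0053), with 2 of 17 members lower over all genes tested and 3 adjusted over the list alone, and its camera call was lost at adjusted p = 0.0957 with an estimated correlation. The Fc receptor-like genes FCRL1 and FCRL5 fell by 0.96 ± 0.24 and 0.36 ± 0.10. The score of genes recurrently deleted in B-precursor leukaemia fell by 0.19 ± 0.08 (31 pairs lower, adjusted p = 0.0441), with 1 of 28 members lower over all genes tested and 6 adjusted over the list alone. That member was ARPP21, which fell by 0.85 ± 0.18, and the camera call of the list gave adjusted p = 0.256 with an estimated correlation. The plasma cell score fell by 0.10 ± 0.04 (30 pairs lower, adjusted p = 0.0441), although 0 of its 14 members passed in limma either over all genes tested or adjusted over the list alone. The B-cell precursor score differed by -0.21 ± 0.10 (29 pairs lower, adjusted p = 0.12) and did not pass, and its camera call gave adjusted p = 0.337 with an estimated correlation. In that list BACH2, a B-cell transcription factor, fell by 0.65 ± 0.16, and CD9 fell by 0.91 ± 0.19 in the probe set used, with 1 of its 3 probe sets pointing that way. Further falls were those of KLF8 (-0.96 ± 0.19), BMP2 (-0.92 ± 0.25), ARID5B, a gene at a known susceptibility locus of this leukaemia (-0.89 ± 0.15), TMED6 (-0.86 ± 0.22), TAGAP (-0.83 ± 0.20) and CRIP1 (-0.81 ± 0.18). The interferon-induced genes IFIT5 and IFIT2 fell by 0.84 ± 0.13 and 0.81 ± 0.22. The chemokine receptor CXCR4, the receptor of CXCL12, fell by 0.25 ± 0.06.

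Outside the lists, SELENOP rose by 1.23 ± 0.28, the steroid-metabolising enzyme AKR1C3 by 1.08 ± 0.24, AIG1 by 1.0 ± 0.20 and transferrin (TF) by 0.99 ± 0.15, the last in 44 of 49 pairs. Genes with a known place in drug response or relapse did not all change. Thymidylate synthase (TYMS) differed by 0.50 ± 0.15 (adjusted p = 0.073), the glucocorticoid receptor NR3C1 by -0.19 ± 0.06 (adjusted p = 0.102), the mismatch repair gene MSH6 by -0.17 ± 0.10 (adjusted p = 0.461), IKZF1 by -0.23 ± 0.13 (adjusted p = 0.394) and CDKN2A by 0.02 ± 0.16 (adjusted p = 0.967). With the same marker scores as covariates 8 genes passed, 1 higher and 7 lower, and the scores of mature B cells (-0.21 ± 0.08), megakaryocytes (0.16 ± 0.06) and stroma (0.15 ± 0.07), all at adjusted p = 0.0898, of plasma cells (-0.08 ± 0.05) and of recurrently deleted genes (-0.13 ± 0.09) did not pass. With the mitosis score as a covariate, 18 genes passed, 6 higher and 12 lower, a variance trend with robust fitting left 183, and without the 2 early pairs out of accession order 191 genes and 9 list scores passed in place of 11.

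**Figure D2:**
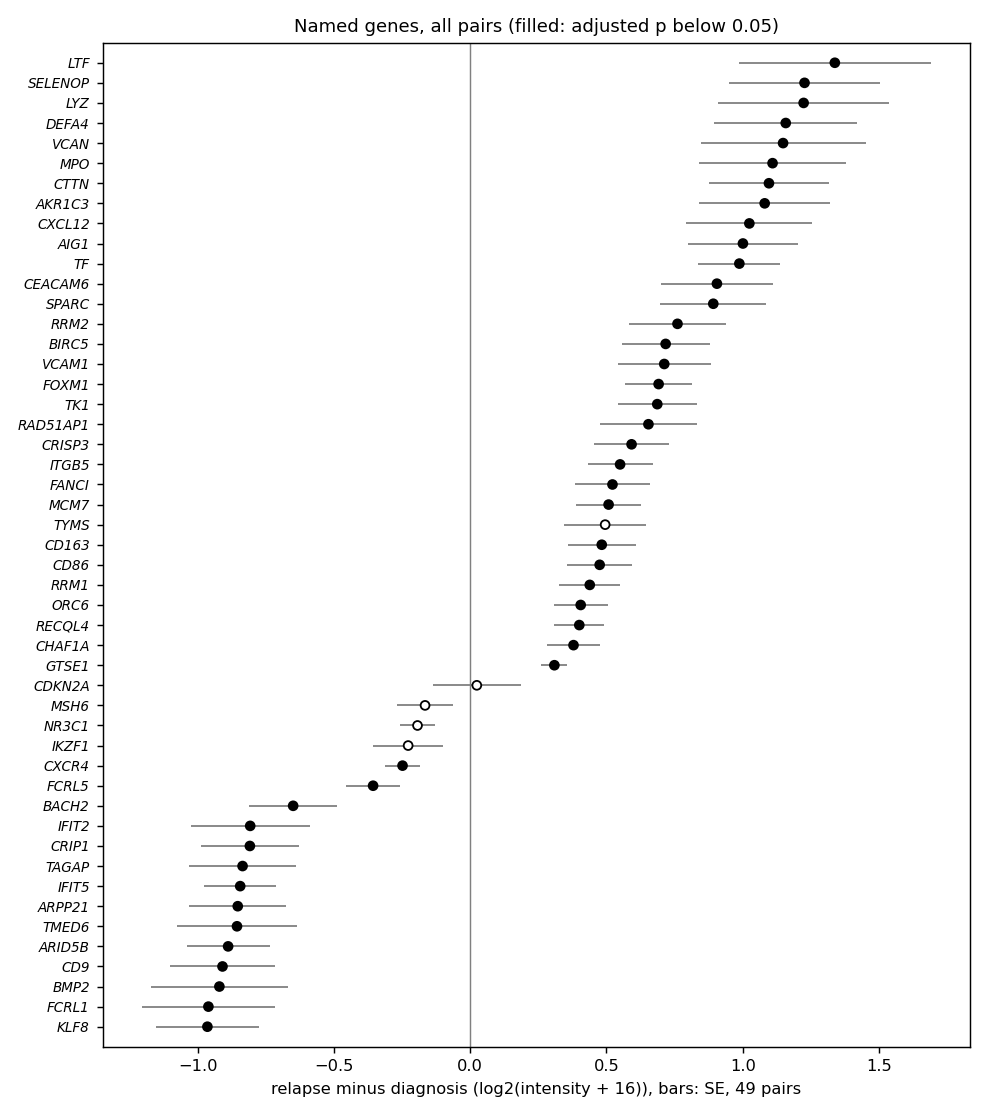
Change from diagnosis to relapse of the genes chosen by the naming rule over all 49 pairs, in log2 units with SE bars. Filled points have an adjusted p below 0.05, as for LTF at 1.34 and KLF8 at -0.96, and open points such as CDKN2A at 0.02 do not.

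The second comparison asked the same of the 29 early relapse pairs alone. Markers of the B lineage were lower at relapse, and markers of monocytes, granulocytes, megakaryocytes and stroma were higher, while 0 single genes passed in limma. At an unadjusted p under 0.05 there were 1876 genes with the pairing and 913 without it (no replicate block). The mature B-cell score fell by 0.33 ± 0.09 (lower in 21 of 29 pairs, adjusted p = 0.0185). Of its 17 members, 0 passed over all genes tested and 3 were lower adjusted over the list alone, and its camera call was kept, at adjusted p = 0.0419 with an estimated correlation. The plasma cell score fell by 0.18 ± 0.06 (21 pairs lower, adjusted p = 0.0244), and the B-cell precursor score fell by 0.37 ± 0.14 (18 pairs lower, adjusted p = 0.0413). Adjusted over the list alone, 0 of the 14 plasma cell and 2 of the 29 precursor genes were lower. Both camera calls gave adjusted p = 0.098 with an estimated correlation. The score of recurrently deleted genes fell by 0.31 ± 0.12 (22 pairs lower, adjusted p = 0.0244), with 3 of 28 members lower adjusted over the list alone, and its camera call gave adjusted p = 0.121 with an estimated correlation. This list and the precursor list share 8 measured genes. With the interquartile range of the array as a covariate the plasma cell score differed by -0.15 ± 0.05 (adjusted p = 0.055). The precursor score then differed by -0.30 ± 0.13 (adjusted p = 0.077) and that of recurrently deleted genes by -0.23 ± 0.10 (adjusted p = 0.0642). None of these passed, while the mature B-cell score did (-0.28 ± 0.08, adjusted p = 0.024). Members that passed adjusted over the list alone, chosen after their values were seen, were FCRL1 (-1.18 ± 0.34) and FCRL2 (-0.75 ± 0.25) of mature B cells, the precursor surface marker CD24 (-0.90 ± 0.28), and ARPP21 (-1.06 ± 0.23).

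In the same early pairs the monocyte score rose by 0.47 ± 0.15 (18 of 29 pairs, adjusted p = 0.0244), the granulocyte score by 0.53 ± 0.18 (20 pairs, adjusted p = 0.0245), the megakaryocyte score by 0.44 ± 0.13 (17 pairs, adjusted p = 0.0239) and the stromal score by 0.29 ± 0.09 (21 pairs, adjusted p = 0.0244). Adjusted over the list alone, 14 of 26 monocyte, 9 of 26 granulocyte, 10 of 20 megakaryocyte and 8 of 23 stromal genes were higher, and 0 of each over all genes tested in limma. MPO (1.22 ± 0.31), CD163 (0.62 ± 0.18), the megakaryocyte tubulin TUBB1 (1.01 ± 0.32) and CXCL12 (1.17 ± 0.33), chosen after their values were seen, passed adjusted over the list alone. In the same order the camera calls gave adjusted p = 0.098, 0.128, 0.121 and 0.128 with an estimated correlation. When the median of the members replaced their mean, 0 list scores passed in the early pairs. With the marker scores of other cell types as covariates 0 of the 6 early lists outside these markers passed, the mature B-cell score differing by -0.33 ± 0.10 (adjusted p = 0.157) and the megakaryocyte score by 0.16 ± 0.08 (adjusted p = 0.157). The scores of plasma cells (-0.19 ± 0.07), recurrently deleted genes (-0.24 ± 0.13), B-cell precursors (-0.25 ± 0.12) and stroma (0.19 ± 0.10) kept from 64.3% to 106% of their change. Mitosis genes differed by 0.34 ± 0.20 as a score (20 pairs higher, adjusted p = 0.336), which did not pass. The 5 genes with the smallest p all had an adjusted p of 0.0743 and did not pass. They were ZDHHC23 (-0.67 ± 0.12, lower in 27 of 29 pairs), RIPOR2 (-0.51 ± 0.10), the cell cycle transcription factor E2F5 (-0.56 ± 0.11), ANO10 (0.37 ± 0.07) and HOMER3 (0.61 ± 0.12). Of the genes with a known place in relapse, FOXM1 differed by 0.51 ± 0.17 (adjusted p = 0.292), BIRC5 by 0.52 ± 0.22 (adjusted p = 0.444), TYMS by 0.23 ± 0.20, NR3C1 by -0.25 ± 0.10 (adjusted p = 0.395), IKZF1 by -0.29 ± 0.18, MSH6 by -0.22 ± 0.16 and CDKN2A by -0.02 ± 0.21.

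The third comparison covered the 20 late relapse pairs. Genes of mitosis, DNA replication, nucleotide synthesis and DNA repair were higher at relapse. In limma, 376 genes passed, of which 231 rose and 145 fell, and 4864 had an unadjusted p under 0.05. Without the pairing (no replicate block) 0 passed, with 1869 at an unadjusted p under 0.05. The mitosis score rose by 0.72 ± 0.17 (higher in 15 of 20 pairs, adjusted p = 0.00543), and 12 of its 32 members rose over all genes tested and 30 adjusted over the list alone. Separase (ESPL1) rose by 1.01 ± 0.19, survivin (BIRC5) by 1.0 ± 0.21, FOXM1 by 0.95 ± 0.17, topoisomerase TOP2A by 1.11 ± 0.26 and the mitotic kinase CDK1 by 1.05 ± 0.26. Other mitotic genes with large rises were KIF18B (1.19 ± 0.26), CEP55 (1.09 ± 0.24) and KIF15 (1.06 ± 0.23), and GTSE1 rose by 0.38 ± 0.06. The DNA replication score rose by 0.49 ± 0.12 (15 pairs, adjusted p = 0.00749), with 9 of 37 members higher over all genes tested and 25 adjusted over the list alone. Examples were GINS1 (1.16 ± 0.24), MCM7 (0.86 ± 0.18) and MCM3 (0.75 ± 0.16). The folate and nucleotide synthesis score rose by 0.45 ± 0.10 (16 pairs, adjusted p = 0.00481), with 8 of 30 members higher over all genes tested and 20 adjusted over the list alone. Thymidylate synthase (TYMS), a target of folate antagonists, rose by 0.88 ± 0.20 (adjusted p = 0.0408), RRM2 by 1.08 ± 0.26, TK1 by 1.02 ± 0.22, the purine synthesis enzyme ATIC by 0.79 ± 0.17 and RRM1, in 1 of its 2 probe sets, by 0.55 ± 0.12. The camera calls of these 3 lists ended at adjusted p = 0.186 with an estimated correlation.

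The homologous recombination and checkpoint score rose by 0.32 ± 0.06 in late pairs (18 of 20, adjusted p = 0.00222), with 6 of 21 members higher over all genes tested and 10 adjusted over the list alone. FANCI rose by 0.84 ± 0.17, BRCA1 by 0.78 ± 0.17 and RAD54L by 0.56 ± 0.12, and the camera call gave adjusted p = 0.154 with an estimated correlation. The mismatch repair score rose by 0.33 ± 0.10 (16 pairs, adjusted p = 0.0189), with 0 of 8 members higher over all genes tested and 4 adjusted over the list alone. Those 4 were RPA1, RPA2, RPA3 and EXO1, of which the RPA genes encode the general single-strand binding protein, whereas MSH6 differed by -0.08 ± 0.12. With the interquartile range of the array as a covariate the mismatch repair score differed by 0.11 ± 0.10 and did not pass (adjusted p = 0.456). The MYC-induced growth score rose by 0.17 ± 0.05 (16 pairs, adjusted p = 0.0189), with CAD of pyrimidine synthesis (0.79 ± 0.20) the 1 of 24 members to rise over all genes tested and 5 adjusted over the list alone. Both camera calls gave adjusted p = 0.347 with an estimated correlation. The oxidative phosphorylation score rose by 0.16 ± 0.06 (16 pairs, adjusted p = 0.0477), with 0 of 32 members higher over all genes tested and 2 adjusted over the list alone, and adjusted p = 0.413 with an estimated correlation. That score kept 7.7% of its change with the interquartile range of the array as a covariate, differing by 0.01 ± 0.05 (adjusted p = 0.919). Further rises included DNAJC1 (1.10 ± 0.18, in all 20 pairs), RAB11FIP3 (1.09 ± 0.22) and WDR76 (1.14 ± 0.29). Falls included ARID5B (-0.95 ± 0.19), the lymphocyte egress receptor S1PR1 (-0.94 ± 0.20), IFIT5 (-0.93 ± 0.22), B3GNT2 (-0.75 ± 0.17), HIVEP1 (-0.74 ± 0.17), RNF111 (-0.72 ± 0.19), SAV1 (-0.68 ± 0.16), C3orf38 (-0.65 ± 0.15), RRAS2 (-0.64 ± 0.17) and TAB2 (-0.62 ± 0.15). NR3C1 (-0.10 ± 0.06), IKZF1 (-0.13 ± 0.16) and CDKN2A (0.09 ± 0.24) did not pass. The B-lineage scores did not pass in the late pairs. Mature B-cell markers differed by -0.13 ± 0.10, recurrently deleted genes by -0.02 ± 0.08, plasma cell markers by 0.01 ± 0.04 and B-cell precursor genes by 0.04 ± 0.12.

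Array properties moved with the late pairs. The interquartile range of log2 values within an array rose by 0.09 ± 0.03 from diagnosis to relapse in the late pairs (13 of 20, permutation p = 0.00212), and differed by -0.05 ± 0.04 in the early pairs (p = 0.269). The granulocyte score differed by 0.45 ± 0.23 in the late pairs (15 of 20, adjusted p = 0.196) and the monocyte score by 0.27 ± 0.18 (adjusted p = 0.328), and neither passed, although CRISP3 of the granulocyte list rose by 0.63 ± 0.16. CRISP3 was dim here too, with means of 5.81 at diagnosis and 6.44 at relapse. Camera called the granulocyte and monocyte lists, at adjusted p = 0.7 and 0.839 with an estimated correlation. With the interquartile range as a covariate 0 of the 7 late list scores passed. Mitosis then differed by 0.65 ± 0.22 (adjusted p = 0.133), DNA replication by 0.21 ± 0.12 (adjusted p = 0.372), folate and nucleotide synthesis by 0.18 ± 0.08 (adjusted p = 0.266), homologous recombination by 0.21 ± 0.06 (adjusted p = 0.158) and MYC-induced growth by 0.05 ± 0.05 (adjusted p = 0.553). The late count of genes fell to 0 with the interquartile range as a covariate, with the mitosis score as a covariate, and with a variance trend and robust fitting. In the same order the 376 genes kept a median of 66.7%, 85.5% and 100% of their change, with 376, 375 and 376 in the same direction, and the smallest adjusted p was 0.56, 0.0846 and 0.0943. The median SE went from 0.11 to 0.12, 0.14 and 0.12. After quantile normalization 148 genes rose and 148 fell, in place of 231 and 145, and without dim probe sets 330 rose and 107 fell.

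**Figure D3:**
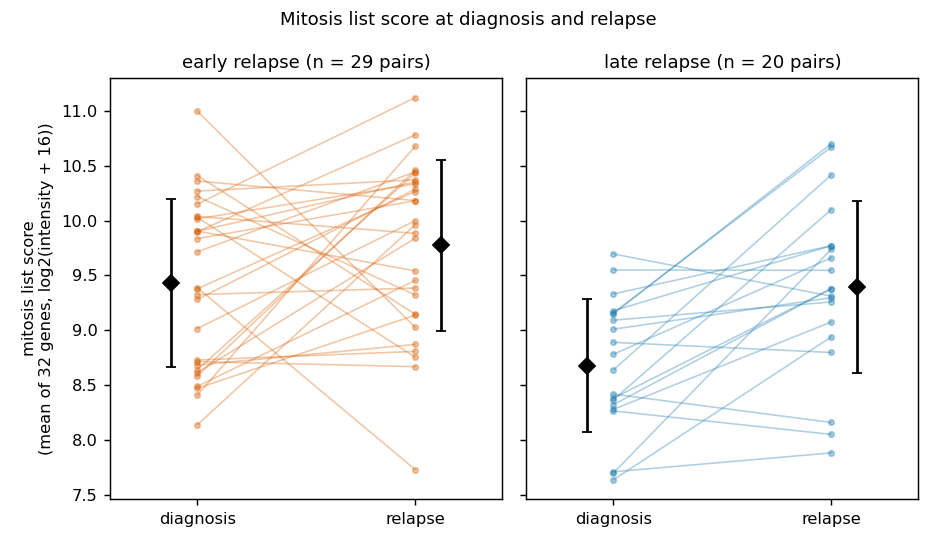
Mitosis list score, the mean log2(intensity + 16) of 32 genes, at diagnosis and relapse. Each line is a pair, with 29 early pairs on the left and 20 late pairs on the right, and diamonds are means with SD. The late group has a mean of 8.68 at diagnosis and 9.40 at relapse, and the early group 9.44 and 9.77.

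The fourth comparison tested whether the change from diagnosis to relapse differed between late and early patients. No difference in the change of a single gene was detected, with 0 genes passing in limma and 2690 at an unadjusted p under 0.05 (980 with no replicate block, that is without the pairing). The change of the mitosis score differed by 0.38 ± 0.27 (late minus early, adjusted p = 0.534), that of folate and nucleotide synthesis by 0.30 ± 0.16 (adjusted p = 0.386) and that of the B-cell precursor list by 0.41 ± 0.19 (p = 0.0391, adjusted p = 0.386). The plasma cell list differed by 0.19 ± 0.08 (p = 0.0168, adjusted p = 0.386), and 0 of 37 list scores passed. The camera test called 16 lists, of which 0 passed with an estimated correlation (smallest adjusted p = 0.417 with an estimated correlation). Of the 376 genes called in late pairs, 271 (72.1%) changed in the same direction in early pairs, and the changes of all genes correlated between the groups at r = 0.311 across genes, which are not independent replicates. The median SD of a gene's change was 0.44 in early and 0.36 in late pairs. The genes with the smallest p, none passing, were LAMA2 (-0.31 ± 0.06, adjusted p = 0.169), SPEF1 (-0.45 ± 0.09), COLQ (0.53 ± 0.11), the splicing factor LUC7L (0.67 ± 0.15) and OSBPL7 (0.77 ± 0.17, where 1 of its 3 probe sets pointed that way). TYMS differed by 0.64 ± 0.30 (adjusted p = 0.343), FOXM1 by 0.44 ± 0.25 (adjusted p = 0.413) and BIRC5 by 0.48 ± 0.33, and NR3C1, MSH6, IKZF1 and CDKN2A differed by 0.12 to 0.16, none passing.

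The fifth comparison set the diagnosis samples of the 20 late patients against those of the 29 early patients, who are different people. Mitosis genes were lower at diagnosis in patients who later relapsed late. The mitosis score was 8.68 ± 0.60 (SD, n = 20) in late and 9.44 ± 0.76 (n = 29) in early patients, a difference of -0.76 ± 0.20 (SE, adjusted permutation p = 0.0233). Of its 32 members, 0 passed over all genes tested and 30 were lower adjusted over the list alone. The proliferation marker MKI67 and the mitotic cyclin CCNB2, chosen after their values were seen, differed by -1.07 ± 0.27 and -1.08 ± 0.27. Camera called 10 lists and 0 passed with an estimated correlation, the mitosis list at adjusted p = 0.076 with an estimated correlation. The scores of DNA replication (-0.45 ± 0.14) and of folate and nucleotide synthesis (-0.42 ± 0.14), both at adjusted p = 0.0601, and of MYC-induced growth genes (-0.21 ± 0.08, adjusted p = 0.0601) did not pass. Single genes numbered 0 in limma, with 1721 at an unadjusted p under 0.05, and array quality weights gave 1889. The genes with the smallest p, all at adjusted p = 0.441, were FOXM1 (-0.88 ± 0.21), the kinase PRKCH (0.93 ± 0.23), SPATA13 (0.79 ± 0.19), NAALADL1 (0.28 ± 0.07) and the clock gene BMAL2 (-0.71 ± 0.17). BIRC5 and TYMS each differed by -0.86 ± 0.24 (adjusted p = 0.483) and CDKN2A by 1.39 ± 0.52 (adjusted p = 0.549), while NR3C1, IKZF1 (both 0.08) and MSH6 (-0.06) differed by less than their SE. The scores of T-cell (0.06 ± 0.16), monocyte (-0.05 ± 0.15), granulocyte (0.06 ± 0.19) and erythroid (0.03 ± 0.28) markers also differed by less than their SE. The interquartile range of the array differed by -0.13 ± 0.08 (p = 0.132).

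The sixth comparison set late against early patients at relapse. No difference in a single gene or list score was detected, with 0 genes in limma and 1244 at an unadjusted p under 0.05. The mitosis score differed by -0.38 ± 0.23 (late minus early, adjusted p = 0.477). Mature B-cell markers differed by 0.33 ± 0.12 (p = 0.00867, adjusted p = 0.321) and antigen presentation genes of MHC class II by 0.33 ± 0.15 (p = 0.0348, adjusted p = 0.477). Camera called 11 lists and 0 passed with an estimated correlation (smallest adjusted p = 0.483 with an estimated correlation). The genes with the smallest p, none passing, were PHYKPL (0.52 ± 0.11), OSBPL7 (0.55 ± 0.12) and PGGHG (1.12 ± 0.25), all at adjusted p = 0.233, and LUC7L (0.55 ± 0.14) and the retinol dehydrogenase RDH5 (0.57 ± 0.14), both at adjusted p = 0.434. CDKN2A differed by 1.51 ± 0.49 (adjusted p = 0.615), FOXM1 by -0.44 ± 0.21 (adjusted p = 0.783), BIRC5 by -0.37 ± 0.24, TYMS by -0.22 ± 0.21, IKZF1 by 0.25 ± 0.24, NR3C1 by 0.23 ± 0.15 and MSH6 by 0.08 ± 0.21. The mean of a gene's probe sets gave 1 gene, PHYKPL, and array quality weights gave 5, which were PHYKPL, OSBPL7, PGGHG, TUBG2 and MICB, named after their values were seen.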

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

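The tests of explanations in this part, and the counts over other splits, were chosen after the results were seen.

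The changes of 3 measures differed between late and early patients by a permutation of the group labels at an unadjusted p, and the list scores among them did not pass adjusted over the lists. The change of the B-cell precursor score was higher in late patients by 0.41 log2 units (p = 0.0391, adjusted p = 0.386 over 37 lists). That of the plasma cell score was higher by 0.19 (p = 0.0168, adjusted p = 0.386). That of the interquartile range of an array was higher by 0.14 (SE 0.05, p = 0.0083).

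Markers of granulocytes, monocytes and megakaryocytes rose at relapse over all 49 pairs, with LYZ going from a mean of 10.5 to 11.7 and MPO from 9.35 to 10.5. A lower share of leukaemic cells that raises all other cell types alike is argued against, because the granulocyte change exceeded the T-cell change by 0.56 ± 0.14 (37 of 49 pairs, p = 0.00013). Scaling between arrays is argued against by a median change of the granulocyte list of 0.46 after quantile normalization. The interquartile range of an array differed by 0.01 ± 0.03 over all pairs (permutation p = 0.731). With so small a mean change, this spread could hardly move the score as a covariate. The score change of 0.49 with it, which passed its test, thus decides nothing about the spread. A different mix of myeloid and stromal cells at relapse, biological or from the handling of the marrow, may stand behind the pattern and was not tested. Of the granulocyte list, 17 of 26 members and of the megakaryocyte list, 15 of 20 lay above the median level of all probe sets, and neither shares a measured gene with another list.

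Genes of cell division and DNA synthesis rose in late pairs. Other cell types in the marrow are argued against as the whole cause in late pairs by a mitosis score change of 0.52 ± 0.12 with their marker scores as covariates (adjusted p = 0.0276), and stay open over all 49 pairs, where mitosis kept 0.188, DNA replication 0.175 and nucleotide synthesis 0.176 and none passed. The spread within an array stays open for each list: with it as a covariate the mitosis score went from 0.72 to 0.646 ± 0.22 (adjusted p = 0.133), that of DNA replication from 0.49 to 0.211 ± 0.12 (adjusted p = 0.372) and that of folate and nucleotide synthesis from 0.45 to 0.178 ± 0.08 (adjusted p = 0.266). The mitosis score correlated with the interquartile range in its change over the 49 pairs (r = 0.404, permutation p = 0.00424, rho = 0.418, p = 0.00297, both the same adjusted over 3 relations, and r = 0.427 without the 2 pairs farthest out), at diagnosis (r = 0.58, rho = 0.597, p = 0.00004, r = 0.539 without 2, n = 49) and at relapse (r = 0.685, rho = 0.67, p = 0.00001, r = 0.709 without 2, n = 49), and the first principal component of the arrays, 23% of the variance, followed the interquartile range at r = 0.939 and the mitosis score at r = 0.621. A higher share of dividing cells at late relapse may also account for the pattern and cannot be told apart from the spread by these covariates. Most interquartile ranges lay below 2.5 or above 2.65, and in most patients both arrays lay on the same side. What separates these 2 sets of arrays was not tested. The correlations at diagnosis and at relapse, and that between the 2 arrays of a patient, may reflect it in part.

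Mitosis genes were lower at diagnosis in late patients. The difference was -0.58 ± 0.18 with the spread as a covariate (adjusted p = 0.0466), so the spread is argued against as the whole cause. With the marker scores of other cell types as covariates it was -0.73 ± 0.21 (adjusted p = 0.0303). Those scores differed by less than their SE between the groups, so they could hardly move the difference, and that fit decides nothing. The speed of division and the share of leukaemic cells per sample were not measured here, so their part in the difference was not tested.

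Over 100 assignments of the samples, the real one included, chance can be excluded for the 291 genes of all pairs (1 split as large, highest other 1) and the 376 genes of late pairs (1 split, highest other 1). The excess of the late over the early count, 376, was reached in 2 splits (highest other 385), and the direct test of the difference of changes called 0 genes. The number of genes at an unadjusted p under 0.05 for the difference of changes, 2690, was reached in 3 splits (highest other 4477). These shares were not adjusted over the counts tested here, and another split gave more genes, so chance is not excluded for either count. The unadjusted count over all pairs, 3140, was reached in 2 splits (highest other 4022), so chance is not excluded for it either. Nor can chance be excluded for the unadjusted count in early pairs (1876, 7 splits, highest other 3661), late against early at diagnosis (1721, 14 splits, highest other 5868) or at relapse (1244, 18 splits, highest other 7257). The 1889 genes at diagnosis with array weights were matched by 19 splits, with 10049 at most. Splits that call several times the real count may point to a structure of the samples other than early and late, or to correlation among genes, and neither was tested. Chance cannot be excluded for the number of lists called by camera at its preset correlation: 16 in all pairs (14 splits as large, highest other 19), 18 in early (8, highest other 20), 10 in late (54, highest other 18), 16 for the difference (19, highest other 26), 10 at diagnosis (45, highest other 19) and 11 at relapse (50, highest other 19).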

How the results depend on the processing

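The covariate for the spread within an array (in genes, lists and scores), no offset before log2, and camera without the block or without the 2 pairs out of order were chosen after seeing the data, the other alternatives before.

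Over all pairs the count of 291 genes became 775 at a threshold of 0.1, 21 with no replicate block, 537 with every probe set, 183 with a variance trend and robust fitting, 949 with array weights, 8 with other cell types and 18 with the mitosis score as covariates, 191 without the 2 pairs out of order, and 704 with the spread. In early pairs 0 became 13 at the threshold of 0.1 and 50 with array weights. In late pairs 376 became 1895 at the threshold of 0.1, 222 with other cell types, and 0 each with no replicate block, with a variance trend and robust fitting, with the mitosis score and with the spread. Of the 222 genes with other cell types as covariates, only 99 were among the 376. The 376 genes then kept a median of 96.2% of their change, all in the same direction, but most lost the call. Array weights gave 3 genes for the difference of changes (ATP2C2-AS1, NAV2 and SPEF1, named after their values were seen), 1889 at diagnosis and 5 at relapse, and the mean of a gene's probe sets gave 1 at relapse. The looser threshold, the larger number of probe sets and the smaller number of pairs change counts by construction, and for the others the cause was not tested.

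Lists called by camera fell with an estimated correlation from 16 to 0 in all pairs, 18 to 1 in early, 10 to 0 in late, 16 to 0 for the difference, 10 to 0 at diagnosis and 11 to 0 at relapse. With fry the counts were 8, 7, 5, 0, 1 and 0, and with the spread 3 lists were called for the difference. List scores passing in early pairs went from 8 to 0 with the median of the members, those in late pairs from 7 to 0 with the spread, and those at diagnosis from 1 to 3 with the median. Here too the cause was not tested.

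The 79 called results of named genes gave 990 values under the alternatives, of which 662 kept the call, 328 lost it and 0 changed direction. The 56 results not called gave 653 values, of which 21 passed. When 20 early pairs were drawn 20 times, between 0 and 14 genes passed, with a median of 0. Intensity near background limits dim genes: 13040 of 19738 genes lay above the median level of all probe sets.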

Other observations

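The count of large falls was tested after the results were seen.

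The lists described here did not pass as scores. Glucocorticoid receptor and induced genes differed by -0.15 ± 0.07 (lower in 30 of 49 pairs, adjusted p = 0.13) with CXCR4 the 1 member to fall over all genes tested, and the list gave adjusted p = 0.269 with an estimated correlation. Interferon response genes differed by -0.17 ± 0.09 (lower in 32 pairs, adjusted p = 0.137; adjusted p = 0.39 with an estimated correlation). In early pairs the score of inflammatory genes of NF-kB differed by 0.27 ± 0.11 (18 of 29 pairs, adjusted p = 0.068), and in late pairs that of Ras pathway feedback genes by -0.15 ± 0.07 (lower in 15 of 20 pairs, adjusted p = 0.17). In late pairs DNMT1, the maintenance DNA methyltransferase, and the histone deacetylase HDAC3, chosen after their values were seen, rose by 0.30 ± 0.07 and 0.31 ± 0.08 (adjusted p = 0.048 and 0.0495), while the score of chromatin regulators differed by 0.01 ± 0.05. The scores of stem and progenitor markers (0.06 ± 0.07) and drug efflux transporters (-0.02 ± 0.03) did not pass over all pairs.

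A hypothesis was that losses of recurrently deleted genes at relapse may show as large falls in some pairs. Over 28 genes and 49 pairs, 185 falls and 105 rises exceeded 1 log2 unit, a difference of 80 (sign-flip permutation p = 0.0519), which leaves it undecided. The count could not have shown losses in any case. The list shares 8 measured genes with the B-cell precursor list, and a lower share of such cells in a sample would also give falls. ARPP21 fell by more than 1 log2 unit in 18 pairs and rose by as much in 3, CD200 in 11 and 4, and LEF1 in 10 and 3. Of the 28 genes, 22 had more such falls than rises, 4 had more rises, as ETV6 (6 and 9) and RB1 (5 and 10) did, and 2 had as many of each.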
